A study of Bacillus subtilis subsp. subtilis str. 168 with 18 samples.

How the data were processed

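Total RNA of Bacillus subtilis and its ywlE and ywlE mcsB mutants was compared on two-colour Agilent arrays. Cultures were grown at 37 °C in a defined medium and taken at an OD500 of 0.4 or 1 h into stationary phase, with 3 biological replicates for each of 3 genotypes and 2 growth phases, 18 arrays in all. Per the labels, the sample was in the Cy5 channel and a common pool in the Cy3 channel of every array. Scanned images were read by the submitters with Agilent Feature Extraction 10.5 and the data were processed in Rosetta Resolver 7.2.1.

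Per the file headers, the deposited gene table holds for each array a linear ratio of sample to pool per annotated gene, an error-weighted average of the probe ratios. The deposited probe table holds log10 ratios of 41882 probes and was used only to check the arrays and the base of its logarithm. Across 153 pairs of arrays, gene-level and probe-level correlations went together with a correlation of 0.9923. No intensities per channel were used here, so signal over background was not assessed. The between-array normalization, the genome build and the position of each probe are not given in the sources used here, and no coordinates are printed.

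The deposited ratios of 4105 genes were put on the log2 scale here, with no further scaling. Gene symbols were taken through the locus tag from a reference gene table: 4037 tags were matched, 68 were not and kept the name in the file, and 1027 genes have a current symbol that differs from that name. In all, 48 gene ratios were exactly 1 and were used as deposited. Group ratios are means of the linear ratios with their SD.

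Comparisons were made with limma 3.58.1 in R 4.3.3. A linear model with 6 group means was fitted to all 18 arrays, with 12 residual degrees of freedom, and moderated with eBayes (prior degrees of freedom 3.32). P-values were adjusted with the Benjamini-Hochberg method over all genes in each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were each mutant against the wild type and the mutants against each other in each phase, the wild type between phases, and the difference between phases of each mutant's effect. The model, the comparisons, the gene lists and the rule for naming genes were fixed before the data were examined.

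The rule for naming genes has 4 parts. It takes ywlE and mcsB, and per comparison the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap over their replicates (for differences between phases, among called genes). It adds up to 4 members with the largest change from each list described, and the neighbours of ywlE and members of the ctsR operon. Features without a symbol were left out. Any gene named outside this rule is marked where it stands.

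In all, 32 lists of regulons, operons and pathways with 660 entries were used, of which 650 were matched. They were tested in each comparison with camera at its preset correlation of 0.01 between genes, and again with the correlation estimated for each list. Adjusted p for lists is over all lists of a comparison. The members of each list were also adjusted over the list alone. The mcsB gene was left out of the CtsR list in comparisons with the labelled double mutant. Overlaps of calls were set against the product of the list sizes over all genes, per direction, and their changes were correlated over all genes and compared with 100 simulations of unchanged groups that share the same arrays. The count of calls shared in these simulations is not used, since unchanged groups give almost no calls.

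The steps were tested on simulated data with a spread taken from these arrays, in which 50 genes were changed by each known fold. Of the genes changed 2-fold, 60% to 90% were recovered in the comparisons between genotypes within a phase. The highest share was for the ywlE mutant against the wild type in exponential growth. The lowest was for the labelled double mutant against the wild type in either phase. Each share rests on 50 simulated genes, so these shares are not read as differences in sensitivity between comparisons. Every simulated group had the same spread of a gene, while the real median SD ran from 0.0753 to 0.377 between groups. The shares therefore do not give the sensitivity of a given comparison in the real data. For the differences between phases of each mutant's effect the shares were 42% for the ywlE mutant and 48% for the labelled double mutant.

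Alternatives fixed beforehand were centring each array on its median, quantile normalization, the replicate number as a block, fitting the arrays of the compared groups alone, eBayes with trend and robust settings, array weights, an adjusted p under 0.01, a minimum change of 2-fold, and leaving out each replicate in turn. For lists, the estimated correlation was among them. Alternatives added after the data were seen were leaving out 3 arrays in doubt, averaging stationary replicates 1 and 2 of the wild type and of the ywlE mutant, setting ratios of exactly 1 to missing, combining the block with the compared groups alone, and testing lists on the compared groups alone. Whether equal replicate numbers mark shared cultures was checked from correlations of the residuals: of all pairs of groups, the wild type and the ywlE mutant in stationary phase alone had every same-number pair above 0.1. The labels do not pair the samples, so no block was used. Figures were drawn with matplotlib 3.10.9 from tables made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.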

Results

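Transcript levels of Bacillus subtilis were measured on 18 two-colour arrays in 6 groups of 3 biological replicates. The wild type, a ywlE mutant and a ywlE mcsB double mutant were each sampled during exponential growth, at an OD500 of 0.4, and 1 h into stationary phase. YwlE is a protein arginine phosphatase that removes the phosphate groups which the kinase McsB places on arginine residues of proteins, so the strains ask how gene expression responds when arginine phosphorylation is no longer reversed or is lost altogether. Each value is the ratio of the sample to a common reference pool for 1 of 4105 genes. Precision is limited by the number of arrays, 3 per group. Changes are on the log2 scale, and every adjusted p is from limma. Unless SD is named, ± is the standard error of the fitted change with 3 arrays in each group. Both rest on 1 spread per gene shared over all groups, although stationary groups varied more than exponential ones.

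The genotype labels were first set against the targeted genes. The ywlE transcript had a mean ratio to the pool of 3.69 ± 0.0554 (SD, n = 3) in exponential wild-type cells and 2.17 ± 0.389 in stationary ones. In the ywlE mutant it was 0.158 ± 0.135 and 0.0575 ± 0.0126, and in the double mutant 0.106 ± 0.0589 and 0.0565 ± 0.0195, each in the same order. Replicate 3 of the exponential ywlE mutant stood at 0.314, against 0.0861 and 0.0738 in the other replicates. In the exponential double mutant replicate 3 stood at 0.173, against 0.0739 and 0.0691. The change of ywlE against the wild type was -4.87 ± 0.46 in the ywlE mutant and -5.26 ± 0.46 in the double mutant in exponential growth, with adjusted p of 1.37e-06 and 2.77e-06. For mcsB the values were mixed. In exponential growth its ratio was 0.473 ± 0.0334 (SD, n = 3) in the wild type and 0.645 ± 0.0493 in the arrays labelled double mutant, a change of 0.45 ± 0.18 (adjusted p = 0.168). In stationary phase mcsB was lower there than in the wild type, at 0.591 ± 0.154 against 1.24 ± 0.0617 (SD, n = 3), a change of -1.10 ± 0.18 (adjusted p = 0.000359). In the ywlE mutant mcsB reached 1.21 ± 0.274 and 1.87 ± 0.0492 in exponential and stationary cells, higher than in these arrays by 0.89 ± 0.18 and 1.69 ± 0.18. The other genes of the operon set a second measure: in exponential growth ctsR, mcsA and clpC changed in these arrays by 2.16 ± 0.19, 1.74 ± 0.18 and 1.88 ± 0.18 against the wild type, while mcsB changed by 0.45. In stationary phase ctsR changed by 0.59, mcsA by 0.36 and clpC by -0.52, while mcsB changed by -1.10. The deleted part of mcsB and the position of its probes are not given in the sources used here, and probes outside a deleted part would check nothing, so these arrays are called the labelled double mutant throughout.

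Exponential and stationary arrays were opposed to each other across genes, with Pearson correlations of the log2 ratios between -0.47 and -0.20 over 81 pairs of arrays. The labels state the dyes of both channels, so the direction of the ratios was kept. Several arrays stood apart from their groups. For replicate 3 of the stationary ywlE mutant, the log2 ratios correlated across genes at 0.729 and 0.733 with the other replicates of its group and at 0.855 to 0.895 with the stationary wild type. Replicate 2 of the stationary labelled double mutant correlated at 0.912 and 0.906 with replicates 1 and 2 of the stationary ywlE mutant, and at 0.825 and 0.904 within its group. Replicate 1 of this group had the widest spread of log2 ratios (SD over genes 1.55) and correlated at 0.825 and 0.852 within its group. In exponential growth, replicate 3 of the labelled double mutant had 11.7% of its probes at a log ratio of exactly 0. Replicates 1 and 2 were closely alike in the stationary wild type (0.993) and in the stationary ywlE mutant (0.991). The median SD of a gene within a group ran from 0.0753 in the exponential wild type to 0.377 in the stationary labelled double mutant.

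**Figure D1:**
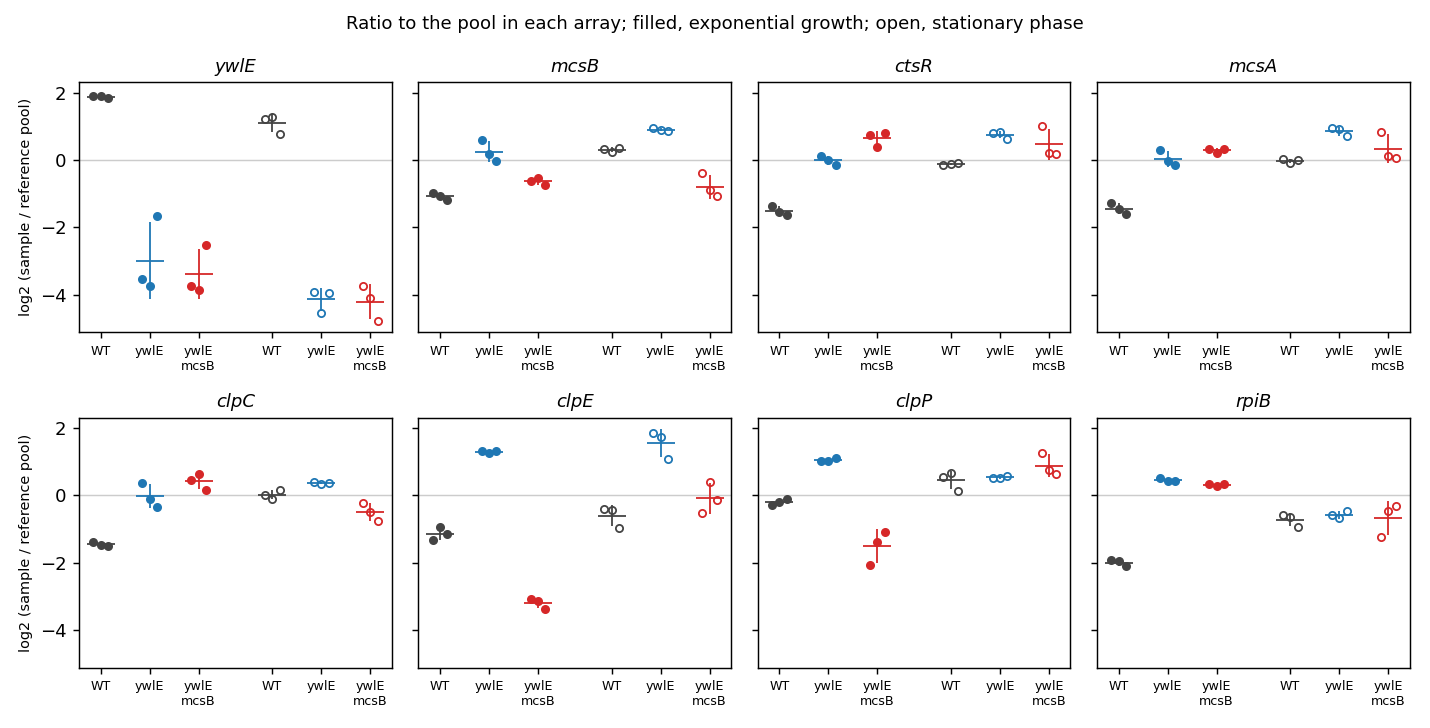
Log2 ratio of sample to reference pool for 8 genes in the 6 groups, with a point for each array and the mean and SD of 3 arrays per group; filled points are exponential and open points stationary cells. The ywlE ratio is low in both mutants, while the mean mcsB ratio in the labelled double mutant is 0.645 in exponential growth against 0.473 in the wild type.

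The comparison of the ywlE mutant with the wild type in exponential growth asked what the loss of the phosphatase changes while cells grow. Genes for DNA uptake and for swimming were higher in the mutant. The competence gene comGA, which encodes the ATPase of the DNA uptake pseudopilus, rose by 5.75 ± 0.30 (53.8-fold), and comGF, in the same operon, by 5.86 ± 0.27. The single-stranded DNA-binding protein gene ssbB rose by 5.66 ± 0.24, the uptake helicase gene comFA by 4.64 ± 0.29 and the DNA receptor gene comEA by 4.43 ± 0.24. The flagellin gene hag rose by 3.42 ± 0.28 (10.7-fold), from a ratio of 0.257 ± 0.0184 to 2.78 ± 0.482 (SD, n = 3 each).

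Of 25 competence genes under the activator ComK, 21 rose (21 adjusted over the list alone), with a median change of 3.94. Camera gave the list an adjusted p of 9.29e-45, and adjusted p = 0.00357 with an estimated correlation. All 31 genes of the motility and autolysin list under the sigma factor SigD rose (31 adjusted over the list alone), with a median of 2.01 (camera adjusted p = 2.41e-56, and adjusted p = 0.00547 with an estimated correlation). Beside hag they included yvyF at 2.60 ± 0.18, the anti-sigma factor gene flgM at 2.57 ± 0.19 and the poly-glutamate hydrolase gene pgdS at 2.43 ± 0.19. The fla/che operon, which encodes the flagellar basal body and chemotaxis proteins, had 17 of 30 members higher (28 adjusted over the list alone), with a median of 1.02 and fliP at 1.21 ± 0.16. Its camera adjusted p was 1.08e-17, but adjusted p = 0.0976 with an estimated correlation.

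CtsR represses the genes of the Clp proteases and of its own operon. Of the 8 genes of its regulon 6 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 1.38 (camera adjusted p = 9.39e-06, but adjusted p = 0.0757 with an estimated correlation). The Clp ATPase gene clpE rose by 2.43 ± 0.24, ctsR by 1.51 ± 0.19, mcsA by 1.48 ± 0.18, the ATPase gene clpC by 1.43 ± 0.18, mcsB by 1.33 ± 0.18 and the protease subunit gene clpP, chosen after its values were seen, by 1.26 ± 0.22. The PBSX defective prophage had 14 of 29 genes higher (21 adjusted over the list alone), among them xkdH at 1.30 ± 0.26, with a median of 0.95 (camera adjusted p = 2.69e-13, but adjusted p = 0.448 with an estimated correlation). In the SigW envelope stress list 6 of 33 genes rose (6 adjusted over the list alone), led by ydjH at 1.31 ± 0.23 and pspA at 1.28 ± 0.15 (camera adjusted p = 0.00315, but adjusted p = 0.609 with an estimated correlation). The LexA SOS list had 5 of 14 genes higher (5 adjusted over the list alone), including the recombinase gene recA at 1.26 ± 0.17. The recA gene is also a member of the ComK list. For the LexA list the camera adjusted p was 0.0131, but 0.0509 when the arrays of these groups were fitted alone, and adjusted p = 0.0804 with an estimated correlation. The SigB general stress list had a median of 1.10 and a camera adjusted p of 1.72e-06, but 1 of its 49 genes was called (1 adjusted over the list alone) and adjusted p = 0.864 with an estimated correlation.

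Next to ywlE on the chromosome, rpiB rose by 2.46 ± 0.19 and ywlG by 2.09 ± 0.21, the called members among 10 neighbours (2 adjusted over the list alone; camera adjusted p = 0.0923). The largest falls were in the yfjABCDEF genes, from -2.15 ± 0.36 for yfjA to -1.47 for yfjF, and in yukE (-1.56 ± 0.30), yukA and yukB, which belong to a type VII secretion locus. The putative lipoprotein gene ycdA changed by -1.50 ± 0.29. Biofilm matrix genes had a median of -0.60 with 1 of 20 lower (1 adjusted over the list alone; camera adjusted p = 0.000133, but adjusted p = 0.609 with an estimated correlation). Carbon catabolite-repressed genes had 8 of 48 higher (12 adjusted over the list alone), with a camera adjusted p of 0.00039, but the direction turned after quantile normalization (adjusted p = 0.116) and adjusted p = 0.609 with an estimated correlation. In all, 355 of 4105 genes were called, 258 higher and 97 lower, and 892 had an unadjusted p below the threshold. After quantile normalization 1133 genes were called, 472 higher and 661 lower, so the larger share of higher calls depended on the scaling. With array weights 1049 were higher and 1499 lower. With the arrays of these groups fitted alone 2181 genes were called, 887 higher and 1294 lower. Leaving out single arrays gave 221 to 323.

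**Figure D2:**
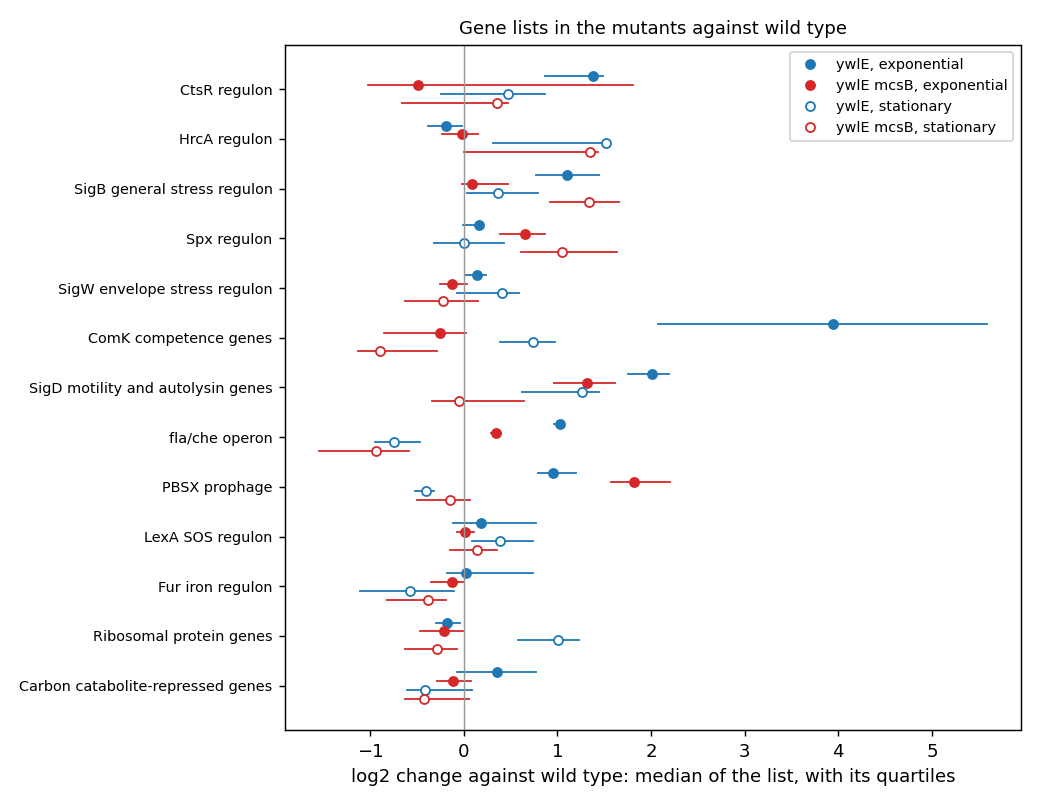
Median log2 change of 13 gene lists (horizontal axis) in each mutant against the wild type, in exponential growth (filled) and stationary phase (open), with lines from the lower to the upper quartile of the list. The ComK list has a median of 3.94 in the ywlE mutant and -0.25 in the labelled double mutant in exponential growth.

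In stationary phase, the same comparison asked what the loss of the phosphatase changes in cells that have stopped growing. The hag gene rose by 3.23 ± 0.28 (9.36-fold), and the motor genes motA and motB by 2.08 ± 0.12 and 1.80 ± 0.14. The chaperonin genes groES and groEL rose by 2.43 ± 0.32 and 2.10 ± 0.25. The alpha-amylase gene amyE changed by -3.19 ± 0.28, the siderophore-binding gene feuA by -2.12 ± 0.23, the flavodoxin gene fldN by -1.81 ± 0.26 and fbpB, part of the iron-sparing response, by -1.93 ± 0.29.

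Of 9 genes under the heat-shock repressor HrcA, 5 rose (5 adjusted over the list alone), with a median of 1.52. Among them grpE changed by 1.56 ± 0.19 and hrcA by 1.53 ± 0.13 (camera adjusted p = 7.74e-06, but adjusted p = 0.259 with an estimated correlation). Of 51 ribosomal protein genes 30 rose and 1 fell (36 and 1 adjusted over the list alone), with a median of 1.01 and rplW at 1.76 ± 0.22 (camera adjusted p = 4.15e-14, but adjusted p = 0.164 with an estimated correlation). The SigD list had 22 of 31 higher and 2 lower (24 and 3 adjusted over the list alone; median 1.26; camera adjusted p = 1.09e-16, but adjusted p = 0.226 with an estimated correlation). The fla/che operon had 16 of 30 lower (17 adjusted over the list alone; median -0.75; camera adjusted p = 1.88e-08, but adjusted p = 0.42 with an estimated correlation). Competence genes were higher in 14 of 25 cases and lower in 1 (15 and 1 adjusted over the list alone). Their median was 0.74, with ssbB at 2.21 ± 0.24 (camera adjusted p = 3.21e-06, but adjusted p = 0.42 with an estimated correlation). The Fur iron list had 12 of 31 lower (15 adjusted over the list alone; median -0.57; camera adjusted p = 1e-06, but adjusted p = 0.623 with an estimated correlation). Early sporulation genes had 9 of 24 higher (9 adjusted over the list alone), among them spoIIQ at 1.23 ± 0.19 (camera adjusted p = 0.0118, but adjusted p = 0.696 with an estimated correlation). In the CtsR list, clpE rose by 2.16 ± 0.24 while the DNA repair gene radA and the diadenylate cyclase gene disA, at the end of the ctsR operon, changed by -1.50 ± 0.15 and -1.20 ± 0.14. In this list 4 of 8 members were higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.373). In all 815 genes were called, 516 higher and 299 lower (1625 and 1632 with array weights). Without replicate 3 of the ywlE mutant 1688 were called, against 326 to 413 without replicate 1 or 2 of either group and 911 without replicate 3 of the wild type. Fitting these groups alone gave 230 (174 higher, 56 lower), and averaging replicates 1 and 2 of each group gave 171.

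The labelled double mutant was set against the wild type in exponential growth to ask what changes in cells labelled as lacking both kinase and phosphatase. The hag gene changed by 2.59 ± 0.28 (6.04-fold), pgdS by 2.46 ± 0.19, and the PBSX genes xkdH and xtmA by 2.41 ± 0.26 and 2.37 ± 0.17. The fructosamine genes frlB and frlO, repressed by CodY, changed by -2.82 ± 0.64 and -2.77 ± 0.45. Within the CtsR list ctsR rose by 2.16 ± 0.19, clpC by 1.88 ± 0.18 and mcsA by 1.74 ± 0.18, whereas clpE changed by -2.06 ± 0.24 and clpP, chosen after its values were seen, by -1.31 ± 0.22. Of its 7 members other than mcsB, 3 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.793).

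The SigD list had 28 of 31 genes higher (30 adjusted over the list alone) and a median of 1.32 (camera adjusted p = 1e-43, and adjusted p = 0.0211 with an estimated correlation). Of 11 genes under the thiol stress regulator Spx 6 rose (9 adjusted over the list alone), with a median of 0.65. They included bdhJ at 1.07 ± 0.17, sufL at 0.99 ± 0.14 and nfrAA at 0.81 ± 0.12 (camera adjusted p = 4.86e-09, and adjusted p = 0.0211 with an estimated correlation). The PBSX list had 25 of 29 higher (25 adjusted over the list alone; median 1.82; camera adjusted p = 8.67e-34, but adjusted p = 0.101 with an estimated correlation). Competence genes had 6 of 25 lower (10 lower and 1 higher adjusted over the list alone; median -0.25), with a camera adjusted p of 0.00491 that became 0.532 after quantile normalization, and adjusted p = 0.667 with an estimated correlation. The DegU list had 3 of 10 lower (7 adjusted over the list alone). Among them were the biofilm hydrophobin gene bslA at -1.92 ± 0.22 and the contact-dependent toxin gene wapA at -1.36 ± 0.25 (camera adjusted p = 7.42e-05, but adjusted p = 0.128 with an estimated correlation). CodY-repressed genes had 5 of 26 lower (5 adjusted over the list alone; camera adjusted p = 0.000397, but adjusted p = 0.667 with an estimated correlation). Cannibalism toxin genes had 1 of 10 lower (1 adjusted over the list alone), skfA at -1.45 ± 0.22 (camera adjusted p = 0.0152, but adjusted p = 0.704 with an estimated correlation). The neighbours rpiB and ywlG rose by 2.32 ± 0.19 and 1.94 ± 0.21. In all 346 genes were called, 214 higher and 132 lower. Quantile normalization gave 742. The excess of higher calls turned with the arrays of these groups alone (824; 378 higher, 446 lower) and with array weights (508 higher, 580 lower), and leaving out single arrays gave 207 to 322.

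In stationary phase the labelled double mutant was again compared with the wild type. The thiol peroxidase gene tpx rose by 3.15 ± 0.17 (8.85-fold), the superoxide dismutase gene sodA by 2.85 ± 0.16, ytxK by 3.22 ± 0.12, yjoA by 3.10 ± 0.13 and groES by 2.61 ± 0.32. The acetoin synthesis genes alsS and alsD changed by -4.84 ± 0.67 and -3.97 ± 0.61, amyE by -3.08 ± 0.28, the fructose transport gene levD by -2.70 ± 0.44 and the aminotransferase gene ilvE by -2.39 ± 0.25.

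Of 11 Spx-regulated genes 8 rose (10 adjusted over the list alone), with a median of 1.05. Beside tpx they included bdhJ at 2.22 ± 0.17 and the thioredoxin gene trxA at 1.52 ± 0.27 (camera adjusted p = 9.87e-08, but adjusted p = 0.0701 with an estimated correlation). The HrcA list had 5 of 9 higher (5 adjusted over the list alone), groEL at 2.35 ± 0.25 and dnaK at 1.43 ± 0.21 among them (camera adjusted p = 0.00464, but adjusted p = 0.721 with an estimated correlation). The fla/che operon had 17 of 30 lower (18 adjusted over the list alone; median -0.94; camera adjusted p = 3.1e-08), with fliK at -1.79 ± 0.28. Competence genes had 17 of 25 lower (17 adjusted over the list alone; median -0.89; camera adjusted p = 2.18e-05), with comFA at -1.54 ± 0.29. For both of these adjusted p = 0.721 with an estimated correlation. Sporulation genes had 11 of 24 higher and 2 lower (11 and 2 adjusted over the list alone), with spoIIQ at 1.81 ± 0.19 and spoIVA at 1.71 ± 0.29 (camera adjusted p = 0.0137, but adjusted p = 0.721 with an estimated correlation). Secreted enzymes had 7 of 11 lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.00505, but adjusted p = 0.721 with an estimated correlation). The SigB list had 18 of 49 higher (18 adjusted over the list alone; median 1.34; camera adjusted p = 2.87e-06, but adjusted p = 0.721 with an estimated correlation). Its call was also lost without the 3 arrays in doubt (adjusted p = 0.0939). These are replicate 3 of the stationary ywlE mutant, replicate 1 of the stationary and replicate 3 of the exponential labelled double mutant. In all 1411 genes were called, 703 higher and 708 lower. Fitting these groups alone gave 513 (302 higher, 211 lower), averaging stationary replicates 1 and 2 of both the wild type and the ywlE mutant gave 937, and without replicate 1 of the wild type 924 were called. The balance of directions moved with single arrays of the labelled double mutant: 765 higher and 452 lower without replicate 1, 716 and 1026 without replicate 3.

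The ywlE mutant was next compared directly with the labelled double mutant, to ask how strains that both have a low ywlE transcript level differ. In exponential growth the ywlE mutant had higher competence genes, with comGA higher by 7.39 ± 0.30 (167-fold) and ssbB by 6.69 ± 0.24. The protease genes clpE and clpP were higher by 4.50 ± 0.24 and 2.57 ± 0.22, the chemoreceptor gene tlpA by 2.08 ± 0.26, frlO by 2.42 ± 0.45 and recA by 1.14 ± 0.17. Lower genes included helP (-1.38 ± 0.22), yqjM (-1.36 ± 0.20), the PBSX gene xtmA (-1.20 ± 0.17) and bdhJ (-0.92 ± 0.17).

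Of the 25 ComK-dependent genes 21 were higher and 1 lower (21 and 2 adjusted over the list alone), with a median of 3.80 (camera adjusted p = 3e-39, and adjusted p = 0.00627 with an estimated correlation). The SigD list had 19 of 31 higher (22 adjusted over the list alone; median 0.57; camera adjusted p = 9.57e-12, but adjusted p = 0.391 with an estimated correlation). The PBSX list had 13 of 29 lower (20 adjusted over the list alone; median -0.88; camera adjusted p = 6.45e-09, but adjusted p = 0.546 with an estimated correlation). Spx-regulated genes had 5 of 11 lower (9 adjusted over the list alone; median -0.58; camera adjusted p = 1.12e-05, but adjusted p = 0.125 with an estimated correlation). In all 596 genes were called, 356 higher and 240 lower in the ywlE mutant. Quantile normalization gave 1387, with 583 higher and 804 lower, fitting these groups alone gave 1232, and leaving out single arrays gave 276 to 464.

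In stationary phase the same mutants were compared. The cysteine desulfurase gene nifS was higher in the ywlE mutant by 4.71 ± 0.53 (26.3-fold), nadB by 4.57 ± 0.54, nadC by 4.08 ± 0.44 and nadA by 3.54 ± 0.34, and the oxalate decarboxylase gene oxdC by 2.71 ± 0.16. Competence genes ssbB and comFA were higher by 3.58 ± 0.24 and 2.58 ± 0.29. The thiol peroxidase gene tpx (-2.61 ± 0.17), its neighbour ytxK (-2.31 ± 0.12) and the superoxide dismutase gene sodA (-2.09 ± 0.16) were lower in the ywlE mutant than in the labelled double mutant.

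Of 11 Spx-regulated genes 10 were lower (10 adjusted over the list alone), with a median of -1.19 (camera adjusted p = 5.88e-11, and adjusted p = 0.0204 with an estimated correlation). Ribosomal protein genes had 36 of 51 higher and 1 lower (39 and 1 adjusted over the list alone), with a median of 1.17 and rplP at 2.00 ± 0.30 (camera adjusted p = 6.34e-17, but adjusted p = 0.0519 with an estimated correlation). Competence genes had 19 of 25 higher and 1 lower (21 and 2 adjusted over the list alone; camera adjusted p = 3.48e-14, but adjusted p = 0.1 with an estimated correlation). The SigD list had 21 of 31 higher (26 adjusted over the list alone; camera adjusted p = 3.8e-15, but adjusted p = 0.224 with an estimated correlation). The SigW list had 21 of 33 higher (21 adjusted over the list alone), with nfeDB at 1.63 ± 0.20 (camera adjusted p = 7.75e-07, but adjusted p = 0.313 with an estimated correlation). In all 894 genes were called, 489 higher and 405 lower in the ywlE mutant. Quantile normalization gave 435, fitting these groups alone 102, and averaging stationary replicates 1 and 2 of both the wild type and the ywlE mutant 568. Without replicate 1 of the labelled double mutant 320 were higher and 429 lower.

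The changes of the ywlE mutant against the wild type were then compared with those against the labelled double mutant, which share the ywlE arrays. In exponential growth 176 genes were called in both in the same direction, 154 higher and 22 lower, and 17 in opposite directions. The 176 became 661 after quantile normalization, 523 without the 3 arrays in doubt and 88 with at least a 2-fold change. Independent lists of these sizes would share 28.0 genes. The correlation of the changes across genes was 0.714 against 0.498 in 100 simulations of unchanged groups sharing these arrays, and their covariance 0.288 against 0.0394, a difference of 0.249. In stationary phase 238 genes were shared, 167 higher and 71 lower, and 43 were opposite, against 91.0 for independent lists. The 238 became 129, 698 and 70 in the same settings. The correlation was 0.246 against 0.498 simulated and the covariance 0.0910 against 0.0393. The mutants' changes against the wild type share the wild-type arrays. In exponential growth 140 genes were called in the same direction and 9 in opposite ones (16.6 in the same direction for independent lists). The correlation was 0.331 against 0.502 simulated and the covariance 0.0992 against 0.0398. In stationary phase these were 434 and 45 (140 for independent lists), with a correlation of 0.604 against 0.497 simulated and a covariance of 0.271 against 0.0392. The simulations gave every group the same spread of a gene, while the median SD of a gene ran from 0.0753 to 0.377 between groups. They therefore do not show what shared arrays alone would give here, and no conclusion is drawn from the simulated values. The shared groups of 3 arrays were not split, so part of each excess over independent lists may come from the shared arrays.

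The wild type was compared between growth phases as a measure of a large change on these arrays. The acetoin dehydrogenase gene acoA rose by 10.12 ± 0.56 and acoB by 8.73 ± 0.46, the gluconeogenic dehydrogenase gene gapB by 8.56 ± 0.34, the threonine dehydrogenase gene tdh by 8.02 ± 0.30 and the ribose transport gene rbsA by 7.89 ± 0.29. The ribosomal protein genes rpsS, rplW and rplV changed by -6.27 ± 0.20, -6.17 ± 0.22 and -6.11 ± 0.19. The ywlE transcript changed by -0.78 ± 0.46 (adjusted p = 0.137) and mcsB rose by 1.39 ± 0.18 (adjusted p = 3.77e-06). For ywlE the shared spread includes the mutant arrays, with a log2 SD of 1.15 in the exponential ywlE mutant. In the wild type it was 0.02 in exponential and 0.27 in stationary cells. The wild-type ywlE ratios did not overlap, at 3.63 to 3.73 in exponential and 1.72 to 2.44 in stationary cells.

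Ribosomal protein genes fell in 50 of 51 cases (50 adjusted over the list alone), with a median of -4.29 (camera adjusted p = 1.26e-20, but adjusted p = 0.0515 with an estimated correlation). Carbon catabolite-repressed genes rose in 43 of 48 cases and fell in 1 (43 and 1 adjusted over the list alone; median 3.64; camera adjusted p = 3.54e-16, but adjusted p = 0.163 with an estimated correlation). All 12 purine and all 10 pyrimidine synthesis genes fell (12 and 10 adjusted over the list alone), with medians of -3.97 and -3.70 and purS at -4.55 ± 0.26. Camera gave them adjusted p of 3.14e-05 and 0.00298, but adjusted p = 0.6 and 0.709 with an estimated correlation. All 9 arginine synthesis genes fell (9 adjusted over the list alone; median -3.77) and all 7 genes of arginine breakdown under RocR rose (7 adjusted over the list alone; median 2.52), with rocB at 3.20 ± 0.26. Their camera adjusted p were 0.00831 and 0.00298, but adjusted p = 0.709 and 0.442 with an estimated correlation. All 9 HrcA-dependent genes fell (9 adjusted over the list alone; median -2.40) and 7 of 8 CtsR-dependent genes rose (8 adjusted over the list alone; median 1.15). Camera adjusted p were 0.000315 and 0.00787, but adjusted p = 0.442 with an estimated correlation for each.

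The Fur iron list had 20 of 31 higher and 7 lower (20 and 7 adjusted over the list alone), with fldN at 6.29 ± 0.26 (camera adjusted p = 0.000315, but adjusted p = 0.709 with an estimated correlation). The SigB list had 37 of 49 higher (37 adjusted over the list alone; camera adjusted p = 4.69e-05, but adjusted p = 0.752 with an estimated correlation). Sporulation genes had 17 of 24 higher and 1 lower (17 and 1 adjusted over the list alone), with spoIIE at 4.99 ± 0.37 (camera adjusted p = 6.81e-05, but adjusted p = 0.6 with an estimated correlation). Competence genes had 19 of 25 higher and 3 lower (19 and 3 adjusted over the list alone; camera adjusted p = 6.81e-05, but adjusted p = 0.589 with an estimated correlation). Fermentation genes had 14 of 18 higher (15 adjusted over the list alone), ATP synthase genes 8 of 9 lower (9 adjusted over the list alone) and PBSX genes 14 of 29 higher (10 adjusted over the list alone). Their camera adjusted p were 0.0146, 0.0222 and 0.0412, but adjusted p = 0.709, 0.709 and 0.879 with an estimated correlation. Secreted enzymes had 7 of 11 higher and 2 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.0222, but 0.0902 with these groups fitted alone and adjusted p = 0.589 with an estimated correlation).

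The remaining lists were not called between phases. The SigD list had 8 of 31 genes higher and 12 lower (6 and 11 adjusted over the list alone) and the fla/che operon 7 of 30 and 17 (7 and 17 adjusted over the list alone). Their camera adjusted p were 0.692 and 0.244. Spx-regulated genes were higher in 6 of 11 cases and lower in 2 (6 and 2 adjusted over the list alone; adjusted p = 0.244). PerR-regulated peroxide stress genes were so in 6 and 4 of 11 cases (6 and 4 adjusted over the list alone; adjusted p = 0.692). Proteases outside the CtsR list were so in 3 and 6 of 9 (3 and 6 adjusted over the list alone; adjusted p = 0.459). SigW genes were higher in 7 and lower in 11 of 33 cases (7 and 11 adjusted over the list alone; adjusted p = 0.852), and matrix genes in 2 and 10 of 20 (2 and 10 adjusted over the list alone; adjusted p = 0.369). Cannibalism genes were higher or lower in 3 and 1 of 10 (2 and 1 adjusted over the list alone, with a camera adjusted p of 0.559). Genes of the DegU list were so in 4 and 1 of 10 (4 and 1 adjusted over the list alone, with a camera adjusted p of 0.288). CodY-repressed genes were higher in 10 and lower in 9 of 26 cases (10 and 9 adjusted over the list alone; adjusted p = 0.559). Citric acid cycle genes were higher or lower in 3 and 3 of 12 (3 and 3 adjusted over the list alone; adjusted p = 0.778) and nitrogen genes under TnrA and GlnR in 5 and 4 of 15 (5 and 4 adjusted over the list alone; adjusted p = 0.852). Phosphate genes under PhoPR were higher in 8 and lower in 2 of 19 cases (8 and 2 adjusted over the list alone; adjusted p = 0.111, and 0.0471 with these groups fitted alone). SP-beta prophage genes were higher or lower in 3 and 19 of 39 (2 and 18 adjusted over the list alone; adjusted p = 0.244). LexA genes were higher or lower in 7 and 3 of 14 (7 and 3 adjusted over the list alone; adjusted p = 0.692) and neighbours of ywlE in 4 and 4 of 10 (4 and 4 adjusted over the list alone; adjusted p = 0.852). In all 3000 genes were called, 1418 higher and 1582 lower in stationary phase.

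Whether the effect of ywlE differed between phases was tested as a difference of differences, stationary minus exponential. The effect on competence genes was smaller in stationary phase, with a difference of -4.92 ± 0.27 for comGG and -4.67 ± 0.42 for comGA. The genes feuA and fldN differed by -2.80 ± 0.33 and -2.75 ± 0.37, rpiB by -2.32 ± 0.27 and the flagellar hook gene flgE by -2.04 ± 0.23. In the other direction ycdA differed by 2.89 ± 0.41, nadA by 2.74 ± 0.48, yukB by 2.50 ± 0.24, rplW by 2.30 ± 0.31 and groEL by 1.78 ± 0.35.

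Of 25 competence genes 20 had a negative difference past the threshold (20 adjusted over the list alone), with a median of -3.16 (camera adjusted p = 5.37e-26, and adjusted p = 0.0346 with an estimated correlation). The fla/che operon had 19 of 30 negative (27 adjusted over the list alone; median -1.78; camera adjusted p = 5.12e-20, but adjusted p = 0.112 with an estimated correlation). Ribosomal protein genes had 24 of 51 positive (32 adjusted over the list alone; median 0.99; camera adjusted p = 9.29e-13, but adjusted p = 0.112 with an estimated correlation). PBSX genes had 16 of 29 negative (26 adjusted over the list alone; camera adjusted p = 1.02e-12, but adjusted p = 0.416 with an estimated correlation). Fur genes had 13 of 31 negative (15 adjusted over the list alone; camera adjusted p = 7.41e-06, but adjusted p = 0.658 with an estimated correlation). HrcA genes had 5 of 9 positive (7 adjusted over the list alone; camera adjusted p = 7.41e-06, but adjusted p = 0.211 with an estimated correlation). In all 596 genes were called, 293 positive and 303 negative. Without replicate 3 of the stationary ywlE mutant 1415 were called, 754 positive and 661 negative, without other single arrays 319 was the lowest count, and averaging stationary replicates 1 and 2 of both the wild type and the ywlE mutant gave 195.

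For the labelled double mutant the same test gave alsS and alsD differences of -5.15 ± 0.94 and -4.41 ± 0.86, and the PBSX genes xkdJ and xtmB -2.68 ± 0.63 and -2.43 ± 0.44. Within the CtsR list clpE and clpP differed by 2.57 ± 0.33 and 1.74 ± 0.31, clpC and ctsR by -2.39 ± 0.26 and -1.57 ± 0.27. The toxin maturation gene sdpB differed by 3.54 ± 0.87, the spore coat gene cotJC by 3.20 ± 0.38, the spore coat assembly gene spoIVA by 2.74 ± 0.41, ytxK by 2.61 ± 0.17 and tpx by 2.45 ± 0.24. PBSX genes had 25 of 29 negative (27 adjusted over the list alone; median -2.05; camera adjusted p = 9.22e-20, but adjusted p = 0.4 with an estimated correlation). SigD genes had 23 of 31 negative (27 adjusted over the list alone; median -1.21; camera adjusted p = 5.8e-20, but adjusted p = 0.369 with an estimated correlation). Sporulation genes had 11 of 24 positive (12 adjusted over the list alone; median 1.05; camera adjusted p = 1.13e-06, but adjusted p = 0.533 with an estimated correlation). In all 531 genes were called, 317 positive and 214 negative, but without replicate 3 of the stationary labelled double mutant 374 were positive and 422 negative. Without the 3 arrays in doubt 1147 were called, and averaging stationary replicates 1 and 2 of both the wild type and the ywlE mutant gave 353.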

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

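The tests on scaling, on the stationary level of motility and competence genes, on the neighbours of ywlE and on the ctsR operon were chosen only after the result was seen.

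The effect of the ywlE mutation differed between growth phases for 596 genes, which stands here because it is a difference between groups tested as such. Of 100 splits that exchange genotype labels within the phases, 1 gave as many genes, the real one, a share under the 0.05 set beforehand. Mixing genotypes removes genotype effects of either phase, so this share cannot tell a difference between phases from an effect common to both. The highest of the others gave 543, but it keeps each genotype group whole and exchanges the labels in 1 phase, so it measures the genotype effect over both phases. The highest split that mixes genotypes gave 481, and it keeps the exponential groups whole. Within this result the competence genes under ComK had a median difference of -3.16 between phases. The difference of the labelled double mutant from the wild type differed between phases for 531 genes. Here 3 of 100 splits gave as many, and the same limit holds. The highest of the others, with 1185, again keeps the groups whole and exchanges the labels in 1 phase. The highest that mixes genotypes gave 576, and it keeps the stationary groups whole.

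For the 7 comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. In exponential growth the count for the ywlE mutant against the wild type was 355 (1 of 10 splits as large; highest other 0), for the labelled double mutant 346 (1 of 10; highest other 0) and for the mutants against each other 596 (1 of 10; highest other 0). In stationary phase it was 815 (1 of 10; highest other 95), 1411 (1 of 10; highest other 6) and 894 (2 of 10; highest other 947). The split with 947 put replicates 1 and 2 of the ywlE mutant with replicate 2 of the labelled double mutant. It left replicate 3 of the ywlE mutant on the other side, which points to a structure of the samples. For the wild type between phases it was 3000 (1 of 10; highest other 0).

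Motility and competence genes were higher in the ywlE mutant in exponential growth, and differences in the centre or spread of the arrays are argued against as the cause, since the lower of the medians of both lists was 2.07 after median centring or quantile normalization. For mutant cultures sampled further towards stationary phase, the slope of the ywlE change on the change between phases in the labelled double mutant was 0.115 over 4019 genes (0.103 to 0.128 leaving out 1 array; 0.0385 after quantile normalization). Ribosomal protein genes had a median of -0.18, a share of 0.0428 of their wild-type change between phases. Beforehand, later sampling was set to show as a slope above 0.1 with ribosomal protein genes lower. A slope and a ribosomal share both below 0.1 were set to speak against it. As worded beforehand, the slope and the sign of the ribosomal median met the condition for later sampling. The ribosomal share was small, the ribosomal list was not called by camera, and the slope was 0.0385 after quantile normalization. These points were not part of that condition. The planned test on the deposited ratios therefore went with later sampling, but does not settle it. If each gene moves one way between the phases, a test chosen afterwards argues against later sampling for these lists. The exponential ywlE mutant lay above the stationary wild type in 31 of 31 SigD and 24 of 25 ComK genes. The lower quartiles of the difference were 1.68 and 1.10. No arrays lie between the sampling times, so a passing rise between them and an effect of the genotype cannot be told apart.

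The neighbours rpiB and ywlG were higher in both mutants in exponential growth. A local effect of the altered ywlE locus of equal strength in both phases is argued against, since the highest stationary change of these genes in either mutant was 0.14. A local effect that depends on the growth phase, and an effect of lost YwlE, stay open and were not tested.

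In the labelled double mutant in exponential growth ctsR, mcsA and clpC were higher but clpE and clpP lower. Readthrough from the altered mcsB locus would not by itself raise ctsR and mcsA, which lie upstream, and the lower of their changes was 1.74. Weaker repression by CtsR of its whole regulon would raise clpE, which changed by -2.06. Both values are part of the pattern itself, so they restate it and are not separate tests. Higher SigB activity is argued against by an upper quartile of 0.47 in the SigB list. The genotype stays open as an explanation and was not tested further.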

How the results depend on the processing

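Leaving out 3 arrays in doubt, averaging replicates, combining the block with the compared groups alone, and setting ratios of 1 to missing were chosen after seeing the data, as was testing lists on the compared groups alone. Counts depended on how the spread was estimated and on the scaling. The model shares 1 spread per gene over groups whose median SD was 0.0753 to 0.180 in exponential and 0.203 to 0.377 in stationary cells. So ± tends to be too wide and adjusted p too large in exponential comparisons. In stationary ones ± tends to be too narrow and adjusted p too small, so calls there tend to be overstated. With the compared groups alone, calls between genotypes rose in exponential growth and fell in stationary phase. The cause of the dependence on scaling was not tested. Median centring, trend and robust settings and ratios of 1 set to missing kept every count of calls within 1.5 times. Another probe summary was not run, since no map from probes to genes was used, nor was a filter on dim genes or an offset, since ratios hold no signal level.

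After quantile normalization, 1133 genes were called for the ywlE mutant and 742 for the labelled double mutant in exponential growth, and 1387 and 435 between the mutants in exponential and stationary cells; the overlaps were 661 and 129. With the compared groups alone, the counts against the wild type were 2181 and 230 for the ywlE mutant (exponential, stationary) and 824 and 513 for the labelled double mutant, between the mutants 1232 and 102, and for the ywlE interaction 964. With array weights from 0.0672 (ywlE stationary 3) to 8.47 (wild-type exponential 2) they were 2548 and 3257 for the ywlE mutant, 1088 for the labelled double mutant and 1637 between the mutants in exponential growth, and 3051 and 1016 for the interactions. Without the 3 arrays in doubt they were 1040 and 2196, 523, and 1122, with 1905 and 1147 for the interactions and overlaps of 523 and 698. With stationary replicates 1 and 2 averaged they were 171, 937 and 568 in stationary phase, and 195 and 353 for the interactions. At an adjusted p under 0.01 they were 209 and 307, 199 and 719, 245 and 450, and 220 and 224 for the interactions. With at least a 2-fold change they were 215 and 278, 173 and 517, 222 and 287, with overlaps of 88 and 70.

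Replicate number as a block gave 360 and 774 for the ywlE mutant, 331 and 1410 for the labelled double mutant, 556 and 837 between the mutants, 2996 between phases and 544 and 530 for the interactions. Pairing is a hint from the wild type and ywlE mutant in stationary phase, with same-number correlations of 0.263 to 0.362 and other-number ones of -0.386 to 0.416. The block lost none of 121 list calls and added 3 among 288 list tests. Block and compared groups alone gave 2320 and 131 for the ywlE mutant, 576 for the labelled double mutant in stationary phase and 100 between the mutants there.

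Leaving out 1 array, with the spread shared over all groups, gave 221 to 323 (ywlE, exponential), 326 to 1688 (ywlE, stationary), 207 to 322 and 924 to 1742 (labelled double mutant), 276 to 464 and 643 to 1110 (between mutants), 2766 to 2907 (phases), and 319 to 1415 and 366 to 796 (interactions). Counts moved by over 1.5 times without these arrays. For ywlE in exponential growth: wild type 2 (235) and 3 (228), ywlE 1 (232) and 2 (221). In stationary phase: wild type 1 and 2 (366 each), ywlE 1 (413), 2 (326) and 3 (1688). For the labelled double mutant: in exponential growth wild type 2 (208) and 3 (207) and its replicate 3 (226), in stationary phase wild type 1 (924). Between the mutants in exponential growth: ywlE 1 (277), 2 (276) and 3 (386), labelled double mutant 2 (347) and 3 (354). For the ywlE interaction: exponential wild type 1 to 3 (360, 369, 397), stationary wild type 1 and 2 (328, 370), exponential ywlE 1 and 2 (366, 337), stationary ywlE 1 to 3 (356, 319, 1415).

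Directions reversed under quantile normalization alone, where the adjusted p was 0.116 for catabolite-repressed genes in the ywlE mutant in exponential growth, and 0.0125 and 0.909 for ribosomal and purine genes in the labelled double mutant in stationary phase. Between the mutants it was 0.0171 and 0.784 for catabolite-repressed and Fur genes in exponential and 0.00586 and 2.75e-06 for pyrimidine and purine genes in stationary cells, and for the labelled double mutant's interaction 0.985 and 0.000392 for Spx and ribosomal genes. Between the mutants in exponential growth dhbA became -0.16, fldN -0.15, spoIIAA -0.27 and spoIIAB -0.32. Of 810 results for named genes, 70 lost their call with the compared groups alone, 87 with the block added, 89 with replicates averaged, 48 with quantile normalization, 15 with array weights, 10 each with centring and without the arrays in doubt, and 6 with the block. Calls gained in these settings, in the same order, numbered 51, 53, 0, 48, 105, 8, 86 and 11. Of 5844 with 1 array left out, 455 lost their call and 86 gained one. Of 121 list calls, 7 were kept with an estimated correlation, 120 with centring, 101 with quantile normalization, 110 without the arrays in doubt and 116 with the compared groups alone. List calls gained with the direction kept numbered 0, 1, 16, 15 and 12 in these settings.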

Other observations

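Beside the iron genes described, feuB and dhbA fell in the stationary ywlE mutant, with changes of -1.75 ± 0.24 and -1.67 ± 0.33 (SE, 3 arrays per group). In the stationary labelled double mutant the flagellar gene fliJ changed by -1.72 and the DNA-binding protein gene ssbB by -1.38 ± 0.24.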
